A study of Mus musculus with 4 samples.

How the data were processed

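Total RNA was measured in 4 samples of mouse dendritic cells, 1 sample in each of 4 groups. Per the labels, the cells carried CD11c, came from animals deficient in interleukin 10 and were kept for 6 h in media alone, with SEA, with LPS or with SEA and LPS together (written SEA/LPS here). The labels give all 4 samples the same lot. They do not name the tissue the cells were grown or taken from, the doses, or separate cultures or animals.

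The values used are the authors' processed table of the whole series, which holds 22690 Affymetrix probe sets for each of the 4 arrays. Judged from the values, the deposited unit is a linear 1-colour array intensity, with 2% trimmed means of 150.1 in each of the 4 columns, so every array had already been scaled to the same mean. The software, background step and scaling rule behind these intensity values as deposited are not given in the sources used here. Scaling to a common mean fixes the average of each array, so a difference in total RNA content between groups cannot be seen in these values. It also sets how many genes read as higher and how many as lower. Scanner files were not analysed here.

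Genes were named through the platform's probe annotation. Of the 22690 probe sets, 64 were array controls, 20380 carried 1 gene symbol, 691 carried several and 1555 carried none. Entrez identifiers of 20351 probe sets matched the gene table of mouse assembly GRCm38.p6, which was used for names only. Probe sets with several symbols or none were left out. The remaining probe sets named 12393 genes.

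The deposited intensities were used without further scaling, since their trimmed means lay within 5% of each other. Signals at or under the 40th percentile of the 4 columns pooled, a signal of 33.3, were set to that floor and log2 was taken. Of several probe sets of a gene, the one with the highest mean floored log2 over the 4 arrays was used, and a gene counted as measured when at least 1 array lay above the floor, which left 9473 genes. A difference against an array at the floor is a lower bound and is written as at least N-fold. Floored values have no order among themselves, so a gene at the floor on both arrays has a difference of 0. List medians count such genes at that 0 and bounds at their bound.

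The comparisons were SEA over media, LPS over media, SEA/LPS over LPS and SEA/LPS over media, together with the SEA difference in the presence of LPS minus the SEA difference without it. With 1 sample per group no test was possible, no p-value or standard deviation is given, and a gene was counted as higher or lower by size alone, at 2-fold or more with the brighter array above the floor. Genes with higher or lower signal under LPS were also taken as sets (LPS-high and LPS-low), on the mean of the LPS and SEA/LPS arrays over media, so that the choice treated both arrays alike. The 95% interval of a set's median describes the spread over its genes only.

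Gene lists were summarised by the median log2 difference of their measured members and by the percentile of that median among 10000 random lists of the same size, matched on mean expression in 10 bins. The central range quoted beside a median runs from percentile 2.5 to percentile 97.5 of those lists. Random lists redraw genes from the same arrays, so a percentile does not measure variation between samples. With this many lists and comparisons, some medians fall outside that range by chance. There were 27 lists, with 466 symbols, of which 414 were named by a probe set. They covered cytokines, chemokines, interferon-stimulated genes, NF-kappaB targets, dendritic cell maturation, both classes of antigen presentation, nitric oxide, prostaglandin and redox enzymes, pattern recognition receptors, alternative activation, the Notch and IL-10 pathways, cell cycle, cholesterol synthesis, glycolysis, oxidative phosphorylation, ribosomal proteins, immediate early and stress genes, dendritic cell identity and markers of 8 other cell types. Some genes stand in more than 1 list. The groups, comparisons, lists, floor, size threshold and all settings below but the last were chosen before the data were examined. Another 5 lists were added later and appear only under the other observations.

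Named genes followed a rule. For SEA over media, LPS over media and SEA/LPS over LPS it took Il10, the 10 highest and 10 lowest genes above the floor on both arrays, the 4 brightest bounds in each direction and up to 4 members of each list with the largest difference. A gene named in one comparison may have its values given in another. Il12a, Fosb, Hspa1a, Ddit3, Ier2, Asns, Scarb1, Cd36, Mrc1, Fcgr3, Tlr7, Mgl2, Gclm, Birc3 and S100a8 lie outside the rule for the comparison they are named in, as do the members spelled out for SEA/LPS over media, and were chosen after their values were seen.

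As a gauge of single probe sets, the other probe sets of a gene that passed the floor were averaged and their direction was set against that of the probe set used. Of the measured genes, 4401 had several probe sets. Comparisons that share an array also share its chance error, so their overlaps and correlations are printed beside 100 simulations of unchanged groups against the shared array and beside the overlap of independent lists. The noise in these simulations was taken from SEA over media, the closest pair of arrays. They hold few called genes, so their overlaps are a low baseline.

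The procedure was tested on simulated data before use. For LPS over media, simulated over 8799 genes with 200 of them changed, the size rule called 60% of 50 genes set 2-fold higher, 100% of those set 4-fold or 8-fold higher and 100% of those set 4-fold lower, and it called 68 of 8599 unchanged genes (0.791%). The simulated list of 20 genes set 4-fold higher reached percentile 100, and a list of 20 unchanged genes lay at percentile 92.0. The changed genes were drawn from brighter genes only, and the noise was taken from SEA over media, the closest pair of arrays. These rates therefore need not hold for genes near the floor or for the other comparisons.

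The results were recomputed with quantile normalization, scaling to the 75th percentile, floors at the 20th and 60th percentiles, log2 of the signal plus the floor, the median of a gene's probe sets, leaving out probe sets marked as cross-hybridising, thresholds of 1.5-fold and 3-fold, and LPS-high and LPS-low sets chosen on a single array. Scaling to the 18 probe sets for hybridisation controls (bioB, bioC, bioD and cre, bacterial and phage transcripts added to the hybridisation mix) was added after these were seen to differ between arrays. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.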

Results

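Gene expression was measured in dendritic cells, the antigen-presenting cells that prime T cells, from mice deficient in interleukin 10 by their label. Cells were kept for 6 h in media alone, with SEA, with LPS or with SEA/LPS, and each of these 4 groups was measured on 1 array. LPS, lipopolysaccharide, is a component of the bacterial outer membrane sensed through the receptor TLR4. The labels do not expand SEA, which in dendritic cell work of this design usually stands for the soluble egg antigen of Schistosoma mansoni, and no value below rests on that reading. The design asks how SEA alone, LPS alone and SEA added to LPS differ from their controls. Since each group had 1 array, no difference below has a replicate check, and the number of arrays limits the precision.

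The median probe set signal was 52.4 in media, 53.2 with SEA, 51.5 with LPS and 45.1 with SEA/LPS, and 60.6%, 61.1%, 60.8% and 57.3% of probe sets lay above the floor. Across genes, which are not independent replicates, the media and SEA arrays were the closest pair (Pearson r = 0.978, with an SD over genes of 0.35 for the log2 difference). The LPS and SEA/LPS arrays followed with r = 0.959, and the media and LPS arrays were farthest apart with r = 0.888. The ratio of 3' to 5' signal of Gapdh, a sign of RNA integrity, was 2.21 in media, 2.69 with SEA, 2.42 with LPS and 3.12 with SEA/LPS. For Actb it was 1.20, 1.37, 1.24 and 1.26. The hybridisation controls were brighter with LPS than with media on 18 of 18 probe sets, by 0.55 log2 on average, and those with SEA/LPS lay between (0.31 log2 over media).

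The Il10 probe set, of the gene in which the animals are labelled deficient, read 37.9 in media, 52.1 with SEA, 304 with LPS and 93.0 with SEA/LPS. All samples share the genotype and the position of this probe set relative to the altered part of the gene is not given in the sources used here, so the reading checks nothing about the labels.

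LPS over media set the scale of the response. The largest differences were in cytokine, chemokine and interferon-response transcripts. Il6, an inflammatory cytokine, was 127-fold higher with LPS (signal 42.3 in media and 5389 with LPS), and Cxcl1, a neutrophil-attracting chemokine, was 58.2-fold higher. Il12b, which encodes the subunit shared by IL-12 and IL-23, was at the floor in media and at least 54.9-fold higher with LPS. Transcripts of the antiviral interferon response were higher by similar factors: Cmpk2 was 83.1-fold, Ifit1 50.6-fold and Rsad2 31.5-fold higher, Ifit2 was at least 105-fold and Oasl1 at least 100.2-fold higher. In all, 574 genes were at least 2-fold higher and 799 at least 2-fold lower among 9473 measured genes.

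Of 16 measured pro-inflammatory cytokines, 14 were higher with LPS and 0 lower (median log2 difference 2.92), among them Il1b (4.34) and Il15 (4.16). Chemokines had 12 of 18 members higher (median 1.98), with Cxcl10 at 5.26, Ccl3 at 3.66 and Cxcl11, at the floor in media, at least 9.07-fold higher. Interferon-stimulated genes had 29 of 32 members higher (median 2.99). In the list of NF-kappaB targets and feedback regulators, 12 of 22 were higher (median 1.11), including Nfkbiz (4.11), Socs3 (2.96), Rel (2.58) and Tnfaip3 (2.29), the last of which encodes an inhibitor of NF-kappaB signalling. Maturation and costimulation genes had 14 of 21 members higher (median 1.65), with Cd40, a costimulatory receptor, at 4.95, Fscn1 at 3.11 and Il15ra at least 17.3-fold higher. The enzymes of nitric oxide, prostaglandin and redox metabolism had 7 of 16 members higher and 1 lower (median 0.78), among them Slc7a2 (2.85), Gch1 (5.64-fold), Ptgs2 (at least 43.8-fold) and Nos2 (at least 8.50-fold), while Gclm was lower (-1.10). All these medians lay at percentile 100 of matched random lists, and each stayed above 0 under every scaling tried.

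Antigen presentation and receptor genes differed less between LPS and media. Class I presentation and immunoproteasome genes had 4 of 13 members higher (Tap1 2.59, Tapbp 2.15, Psmb10 1.69, Tap2 1.19) and a median of 0.34, which was -0.21 when scaled to the hybridisation controls. Class II presentation genes had 0 members higher and 1 of 12 lower, H2-DMa at -1.49, and a median of 0.17 that turned to -0.03 under quantile normalization and -0.38 under scaling to the hybridisation controls. Pattern recognition and uptake receptors had 4 of 21 members higher and 5 lower (median -0.22, percentile 21.8), with Cd14 (1.79), Marco (1.68), Tlr7 (1.32) and Tlr3 (at least 3.87-fold) against Clec4a2 (-1.52), Scarb1 (-1.22), Cd36 (-1.21), Mrc1 (-1.18) and Fcgr3 (-1.06). Of 20 genes of alternative activation and Th2 responses, 2 were higher (Tnfsf4 2.14, Ccl22 1.65) and 4 lower (Egr2 -1.91, Klf4 -1.35, Mrc1 -1.18, Mgl2 -1.13), with a median of -0.13. In the IL-10 pathway list 4 of 14 members were higher (Il1rn 3.27, Socs3 2.96, Stat3 1.34 and Il10 at the signals given above), and its median of 0.33 was -0.23 under scaling to the hybridisation controls. Of 12 Notch pathway genes, Jag1 (1.35) was higher and Psen2 (-1.20) lower, and the median of 0.47 was -0.02 under scaling to the hybridisation controls.

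Cell cycle genes were lower with LPS, with 7 of 23 members at least 2-fold lower, 0 higher and 21 below 0 (median -0.73, percentile 0, negative under every scaling tried). Among these were Ccna2 (-1.59), Cdk1 (-1.56), Ccnb2 (-1.44) and Birc5 (at least 3.15-fold lower), which act in mitosis. Cholesterol synthesis genes had 2 of 13 members lower (Sqle -1.54, Mvd at least 4.69-fold), 1 higher (Idi1 1.21) and a median of -0.41 at percentile 7.65; without cross-hybridising probe sets Mvd read -0.13. Glycolysis and hypoxia genes had 3 of 17 members lower (Slc2a1 -1.51, Slc16a3 -1.20, Pfkl -1.12; median -0.18). Immediate early and stress genes were split, with 4 of 18 higher (Gadd45b 2.36, Hspa1b 1.61, Hspa1a 1.35, Fosb at least 2.12-fold) and 5 lower (Jun -2.08, Egr2 -1.91, Ier2 -1.52, Asns -1.01, Ddit3 at least 2.98-fold). Oxidative phosphorylation genes had 1 of 21 members lower (Sdhd -1.10; median -0.11, which was 0.03 when scaled to the 75th percentile), and ribosomal proteins had 0 of 12 past 2-fold (median -0.19). Dendritic cell identity genes had 2 of 13 members higher (Irf8 1.96, Ly75 at least 2.55-fold), 1 lower (Itgam -1.11) and a median of -0.11, which was 0.03 when scaled to the 75th percentile. The lowest single genes above the floor on both arrays were Idh1 (-4.16, signal 2390.4 in media and 134 with LPS), Gtf2i (-3.23), Tpcn1 (-3.14), Ccr2 (-3.12), Olfm1 (-2.90), Ski (-2.90), Rusc1 (-2.80), Eps8 (-2.68), Arrb1 (-2.65) and Pdk1 (-2.56). Idh1 encodes an isocitrate dehydrogenase and Ccr2 a chemokine receptor. Other probe sets gave smaller sizes for some of these. Idh1 read -2.37 and Gtf2i -1.21 on another probe set above the floor, and those of Rusc1 read 0.12, -0.001 and -1.10. Among genes at the floor with LPS, Map4k1 was at least 7.91-fold, Slc1a5 at least 7.78-fold, Lpin1 at least 6.34-fold and Ppargc1b at least 6.08-fold lower.

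The other probe sets of the called genes pointed the same way for 193 of 215 genes that were higher (89.8%) and 246 of 301 that were lower (81.7%), against 43.8% and 53.4% for random genes. The split between higher and lower depended on the scaling: 41.8% of the called genes were higher as deposited, 55.4% when scaled to the 75th percentile and 10.5% when scaled to the hybridisation controls, which moved the median of all genes from -0.06 to -0.56.

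SEA alone gave a small difference from media, with a few inflammatory genes among the highest. Il6 was 3.30-fold higher with SEA (signal 42.3 and 139.5, or 1.72 log2), Il1b, another inflammatory cytokine, was 2.77-fold higher (signal 367 and 1016) and Cxcl1 was 2.42-fold higher. Egr1, an immediate early transcription factor, was 3.51-fold higher with SEA, while its difference with LPS over media was -0.90. Oasl1, an interferon-stimulated gene, was at the floor in media and at least 4.87-fold higher. Among 9473 genes 61 were at least 2-fold higher and 60 lower.

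Of the 16 cytokines, Il6 and Il1b were the 2 higher with SEA, Il15 (0.98) and Tnf (0.90) lay just under 2-fold, and the median was 0.03. Chemokines had 1 of 18 members higher, Cxcl1 at 1.27, with Cxcl2 at 0.97 and Ccl8 at 0.81 (median 0.04, percentile 68.8). Interferon-stimulated genes had Oasl1 alone of 32 past 2-fold, with Iigp1 at 0.86, Irf7 at 0.80 and Ifi204 at least 1.66-fold higher, and a median of 0.11 at percentile 97.4. No member of the NF-kappaB list passed 2-fold and 14 of 22 were below 0 (median -0.10, percentile 5.58), with Dusp1 at 0.90, Socs3 at 0.86 and Nfkbiz at 0.85 against Nfkbib at -0.67. Maturation and costimulation genes had 0 of 21 members past 2-fold (median 0.03). The dendritic cell identity list had a median of -0.32 at percentile 0.12 with 0 of 13 members past 2-fold, led by Sirpa (-0.55), Cd209a (-0.46), Itgam (-0.36) and Batf3 (-0.36). Class I presentation genes had a median of -0.18 at percentile 1.16, with 11 of 13 members below 0. Receptors had a median of 0.16 at percentile 98.6, with Cd14, the LPS co-receptor, just under 2-fold (signal 1559 and 3112) and Tlr4 at 0.46, against Scarb1 at -0.57 and Marco at -0.54. These last 3 medians kept their sign under every scaling tried.

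Other lists showed little with SEA. Class II presentation had 1 of 12 members lower, Ciita, the transactivator of the class (-1.08). The enzymes of nitric oxide, prostaglandin and redox metabolism, alternative activation, the Notch and IL-10 pathways, cell cycle, cholesterol synthesis, glycolysis, oxidative phosphorylation and ribosomal proteins had 0 members past 2-fold, with medians between -0.04 and 0.11. Egr1 was the only one of 18 immediate early and stress genes past 2-fold (median -0.06). Remaining genes among the 10 highest were Pih1d1 (1.66), D8Ertd738e (1.51), Hdgfl1 (1.45), Bag3 (1.34), Zmynd11 (1.30) and Rtbdn (1.26). The 10 lowest were Ddit4 (-1.50), Rxrb (-1.41), Gtpbp1 (-1.39), Gp2 (-1.34), Oxa1l (-1.31), Prdm4 (-1.30), Sh3gl2 (-1.27), Cab39l (-1.27), Sec24b (-1.26) and Trim35 (-1.24). Of genes at the floor in media, Ciapin1 was at least 4.21-fold, Stc1 at least 2.90-fold and Gckr at least 2.69-fold higher. Of those at the floor with SEA, Runx3 was at least 4.68-fold, Wdr36 at least 4.59-fold, Fbxl15 at least 3.68-fold and Itga5 at least 2.99-fold lower.

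Single calls in this comparison had little backing from other probe sets, which pointed the same way for 4 of 13 genes that were higher and 8 of 18 that were lower, against 40.6% and 42.6% of random genes. The rest did not all point the opposite way: the median difference on the other probe sets was 0 for higher and for lower genes. On its other probe sets Zmynd11 read -0.60 and Cab39l 0.20, opposite to the values above. Il6, Il1b, Cxcl1 and Oasl1 had no other probe set, so this gauge did not reach them.

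**Figure D1:**
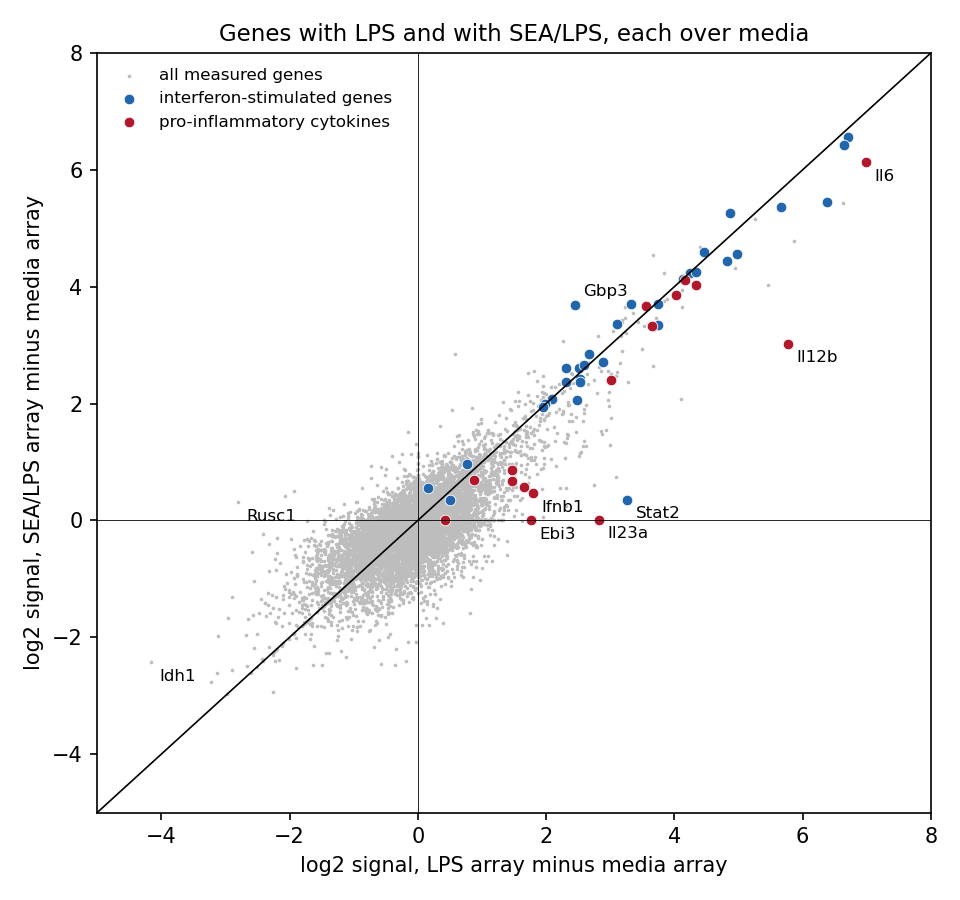
Each point is a gene, with the log2 signal difference of the LPS array over the media array on the x axis and of the SEA/LPS array over the media array on the y axis; grey points are all 9473 measured genes, blue points interferon-stimulated genes and red points pro-inflammatory cytokines, and the diagonal marks equal differences. Il12b, Il23a, Ebi3, Ifnb1 and Stat2 lie under the diagonal, while most interferon-stimulated genes lie close to it.

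SEA/LPS over LPS asks how SEA alters cells that also meet LPS. Il23a and Il12b, which encode subunits of IL-12 family cytokines, were among the 10 lowest genes. Il23a was 7.01-fold lower with SEA/LPS than with LPS (signal 236 with LPS and 33.6 with SEA/LPS), Il12b was 6.74-fold lower (1827 and 271) and Ebi3, another subunit gene of the family, had a difference of -1.75 (1407 and 417). With SEA/LPS, Il23a stood just above the floor and Ebi3 differed from media by 0.01 log2. Nos2, the inducible nitric oxide synthase, was 5.08-fold lower, and Stat2, a transcription factor of type I interferon signalling, was 7.50-fold lower. The other probe set of Stat2 gave a smaller size, -1.67 log2. Among 9473 genes 132 were at least 2-fold higher and 329 at least 2-fold lower.

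Of 16 cytokines 5 were lower and 0 higher with SEA/LPS than with LPS, 15 were below 0 and the median was -0.61, at percentile 0 of matched random lists and -0.37 when scaled to the hybridisation controls. Besides the 3 subunits above these were Ifnb1 (-1.33), which encodes interferon beta, and Il12a (-1.09), which lies outside the naming rule and was chosen after its value was seen. Il6 (-0.86), Il1b (-0.32) and Tnf (0.11) were within 2-fold. Chemokines had 2 of 18 members lower (Cxcl1 -1.08, Ccl3 -1.03) and a median of -0.36 at percentile 0.03. NF-kappaB targets and feedback regulators had 6 of 22 members lower and 1 higher (median -0.29, percentile 0.04), with Nfkbib at -1.89, Nfkb2 at -1.63, Dusp2 at -1.36 and Rel at -1.23 against Birc3 at 1.10. Maturation and costimulation genes had 2 of 21 members lower, Il12b and Cd70 (-1.12), and a median of -0.31 at percentile 0.27. The chemokine, NF-kappaB and maturation medians stayed below 0 under every scaling tried, at -0.15, -0.05 and -0.07 under scaling to the hybridisation controls.

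Interferon-stimulated genes stood near their LPS level, with 1 of 32 members higher (Gbp3 1.25) and 1 lower (Stat2 -2.91). Cmpk2 was at -0.92 and Oas1a at -0.42. The median of the list was -0.02 at percentile 16.6, and it turned to 0.05 when scaled to the 75th percentile and 0.22 when scaled to the hybridisation controls.

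Class I presentation and immunoproteasome genes had 3 of 13 members lower and 0 higher (median -0.67, percentile 0, negative under every scaling tried). These were Psmb8, a catalytic immunoproteasome subunit (-1.98, signal 2895 with LPS and 732 with SEA/LPS), Tapbp, the chaperone tapasin (-1.21), and H2-K1, a class I heavy chain (-1.17). Class II presentation had 1 of 12 members lower, H2-Ab1 at -1.24 (signal 8109 and 3437), with H2-Eb1 at -0.72 and Ciita at -0.68 against H2-DMa at 0.68, and a median of -0.22 that was 0.02 when scaled to the hybridisation controls. The other probe sets of H2-Ab1, H2-K1 and Tapbp read the same direction. All probe sets of H2-K1, the one used included, are marked as able to cross-hybridise, as is the one used for H2-Ab1, which read -1.66 without such probe sets.

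In the list of nitric oxide, prostaglandin and redox enzymes 4 of 16 members were lower, Nos2 (-2.35), Ptgs2 (-1.42), the arginine transporter Slc7a2 (-1.33) and Ncf1 (-1.28), and the median of -0.14 was 0.10 when scaled to the hybridisation controls. Pattern recognition and uptake receptors had a median of 0.52 at percentile 100, with 1 of 21 members higher (Clec4a2 1.02) and 15 above 0, among them Tlr4 (0.99), Clec7a (0.97) and Fcgr3 (0.90), and their median stayed above 0 under every scaling tried. In the IL-10 pathway list 2 of 14 members were lower, Il10 (-1.71) and Stat3 (-1.16), and the median was 0.01. Immediate early and stress genes had 3 of 18 members lower (Gadd45b -2.47, Atf4 -1.47, Dnajb1 -1.15) and 1 higher (Egr2 1.32). The other probe sets of Gadd45b read -1.33 and -0.07. The list median of -0.24 was 0.00 when scaled to the hybridisation controls.

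Metabolic and proliferation lists had few members past 2-fold. Cell cycle had 1 of 23 higher, Cdk1 at 1.07 (median 0.00), cholesterol synthesis 1 of 13 higher, Mvd at least 2.98-fold but -1.05 without cross-hybridising probe sets (median 0.04), glycolysis 1 of 17 lower, Slc16a3 at -1.03 (median 0.15), and oxidative phosphorylation 1 of 21 lower, Uqcrc1 at -1.02 (median 0.26). Ribosomal proteins had 0 of 12 members past 2-fold (median 0.22), Notch pathway genes 0 of 12 (median -0.09) and alternative activation genes 1 of 20, Egr2 (median 0.03). Dendritic cell identity had 1 of 13 lower, Irf8 (signal 1911 and 955; median -0.27, percentile 5.58).

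The remaining single genes among the 10 lowest were Tnfrsf13b (-2.39), Rabac1 (-2.23), Edn1 (-2.15), Sars (-2.12) and Sh3tc1 (-2.08). Akap8l was at least 4.45-fold, Phgdh at least 4.15-fold, Cplx2 at least 3.98-fold and Tmem94 at least 3.86-fold lower. The 10 highest were Rusc1 (3.12), Fen1 (2.48), Ciapin1 (2.27), Rnasek (2.18), Zdhhc12 (1.92), Tnpo1 (1.91), Idh1 (1.74), Jade1 (1.72), Zfp991 (1.67) and Pom121 (1.66). Clip4 was at least 5.42-fold, Crcp at least 4.11-fold, Abca3 at least 3.15-fold and Cops4 at least 3.01-fold higher. The other probe sets of Rusc1 read -0.34, of Fen1 -0.11, of Ciapin1 -0.14 and of Clip4 -0.37, opposite to the values given. Those of Sars read 0.09, and that of Idh1 read 0.26.

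Other probe sets pointed the same way for 73 of 96 genes that were lower (76.0%) and 28 of 49 that were higher (57.1%), against 50.2% and 41.2% of random genes. Of the called genes 28.6% were higher as deposited, 43.3% after quantile normalization, 39.5% when scaled to the 75th percentile and 69.1% when scaled to the hybridisation controls, which moved the median of all genes from -0.01 to 0.11.

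**Figure D2:**
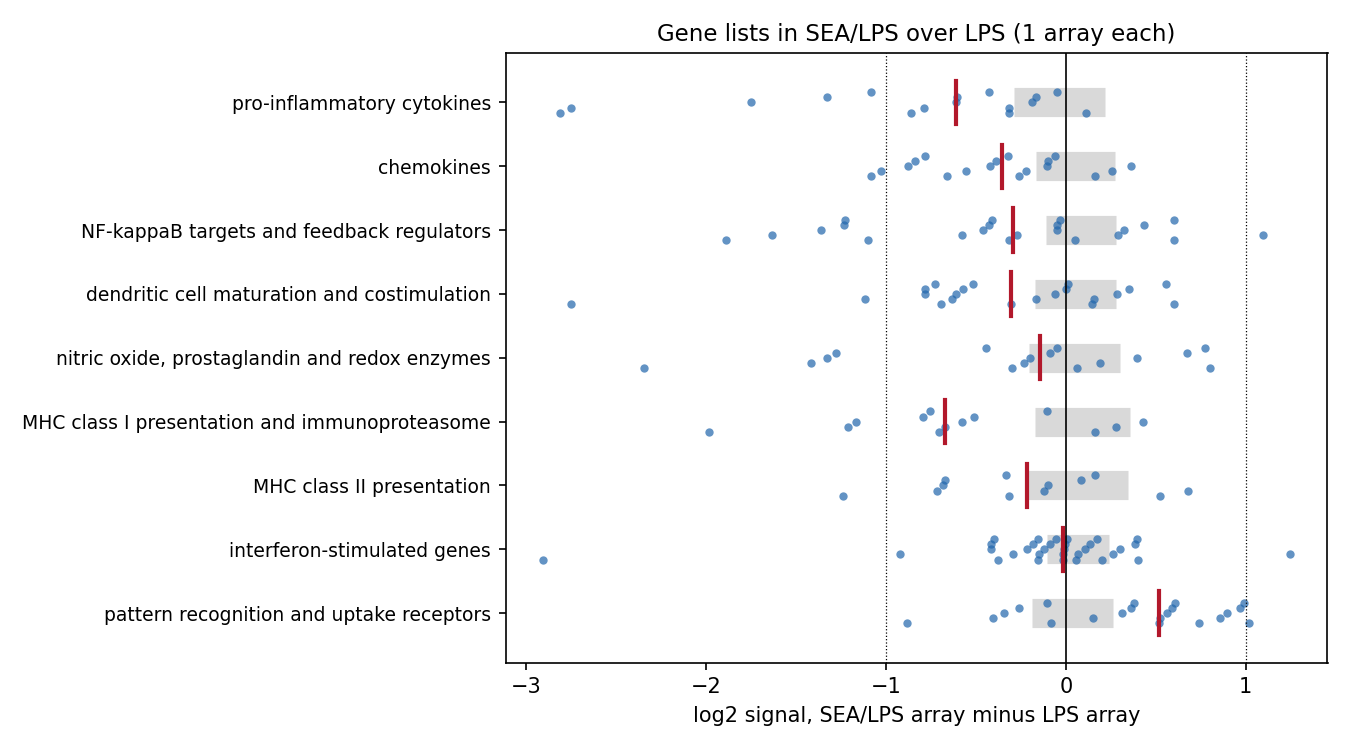
Log2 signal difference of the SEA/LPS array over the LPS array (x axis) for the measured members of 9 gene lists; each blue point is a gene, red bars are list medians, grey bands are the central 95% of medians of 10000 matched random lists and dotted lines mark 2-fold. The cytokine median of -0.61 and the class I presentation median of -0.67 lie under their bands and the receptor median of 0.52 lies above its band; the interferon-stimulated median of -0.02 lies within its band and is above 0 under 2 of the 3 other scalings.

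Genes that were higher with LPS were taken as a set on the mean of both LPS arrays over media. In these 437 genes the median of SEA/LPS over LPS was -0.16 (95% interval over genes -0.21 to -0.10), with 66.6% of them below 0, 43 at least 2-fold lower and 4 at least 2-fold higher. The set included 13 cytokines with a median of -0.61, or 65.4% of the LPS signal, and 29 interferon-stimulated genes with a median of -0.02, or 98.8% of it. For the 612 genes lower with LPS the median was 0.07 (95% interval 0.01 to 0.14), with 45 at least 2-fold higher and 24 at least 2-fold lower. The first median was 0.07 when scaled to the hybridisation controls, and both depended on how the sets were chosen: on the LPS array alone they were -0.38 and 0.43, and on the SEA/LPS array alone -0.01 and -0.29.

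Against media, cells with SEA/LPS were also highest in cytokine and interferon-response transcripts. Il6 was higher by 6.13 log2 and Cmpk2 by 5.46, and Ifit2 was at least 94.2-fold and Oasl1 at least 86.1-fold higher. Stat2 was higher by 0.36, Il12b was at least 8.14-fold higher and Nos2 at least 1.67-fold. On its other probe set, at the floor in media, Stat2 was higher by at least 0.998 log2. A total of 430 genes were at least 2-fold higher and 668 lower. The share of called genes that were higher was 39.2% as deposited, 52.0% after quantile normalization, 58.6% when scaled to the 75th percentile and 16.5% when scaled to the hybridisation controls, which moved the median of all genes from -0.12 to -0.42.

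By list, 28 of 32 interferon-stimulated genes were higher with SEA/LPS than in media (median 3.10), as were 8 of 16 cytokines (median 1.63), 11 of 18 chemokines (1.51), 12 of 21 maturation genes (1.14), 9 of 22 NF-kappaB targets (0.69, with Ier3 lower at -1.17) and 5 of 16 nitric oxide, prostaglandin and redox enzymes (0.66, with Ncf1 lower at -1.76), the 5 being Gch1 (2.56), Acod1 (1.80), Slc7a2 (1.53), Slc7a11 (1.46) and Ptgs2 (at least 16.4-fold). All 6 medians lay at percentile 100 and stayed above 0 under every scaling tried. Cell cycle genes had 5 of 23 members lower (median -0.65, percentile 0.06, negative under every scaling tried): Ube2c (-1.98), Cdc20 (-1.65), Plk1 (-1.25), Mcm7 (-1.09) and Mcm6 (-1.06).

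Genes higher over media with LPS and with SEA/LPS overlapped in 334 genes, or 58.2% of the 574, where independent lists would share 26.1 and simulated unchanged groups shared 2.18 on average. For lower genes the overlap was 356, against 56.3 and 4.19. The differences correlated across genes with r = 0.79 (simulated 0.50) and a covariance of 0.438 (simulated 0.0554). LPS and SEA shared 17 higher genes, Il6, Il1b, Cxcl1 and Oasl1 among them, against 3.70 for independent lists and 2.09 in simulation, with r = 0.27 (simulated 0.50) and a covariance of 0.0736 (simulated 0.0554). Of genes higher with LPS, 105 were lower with SEA/LPS than with LPS, against 19.9 and 4.37, and of genes lower with LPS 94 were higher, against 11.1 and 2.04. All these pairs share an array, which could not be split, so part of each excess may come from it. The simulated overlaps hold few called genes and do not measure how large that part is.

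**Figure D3:**
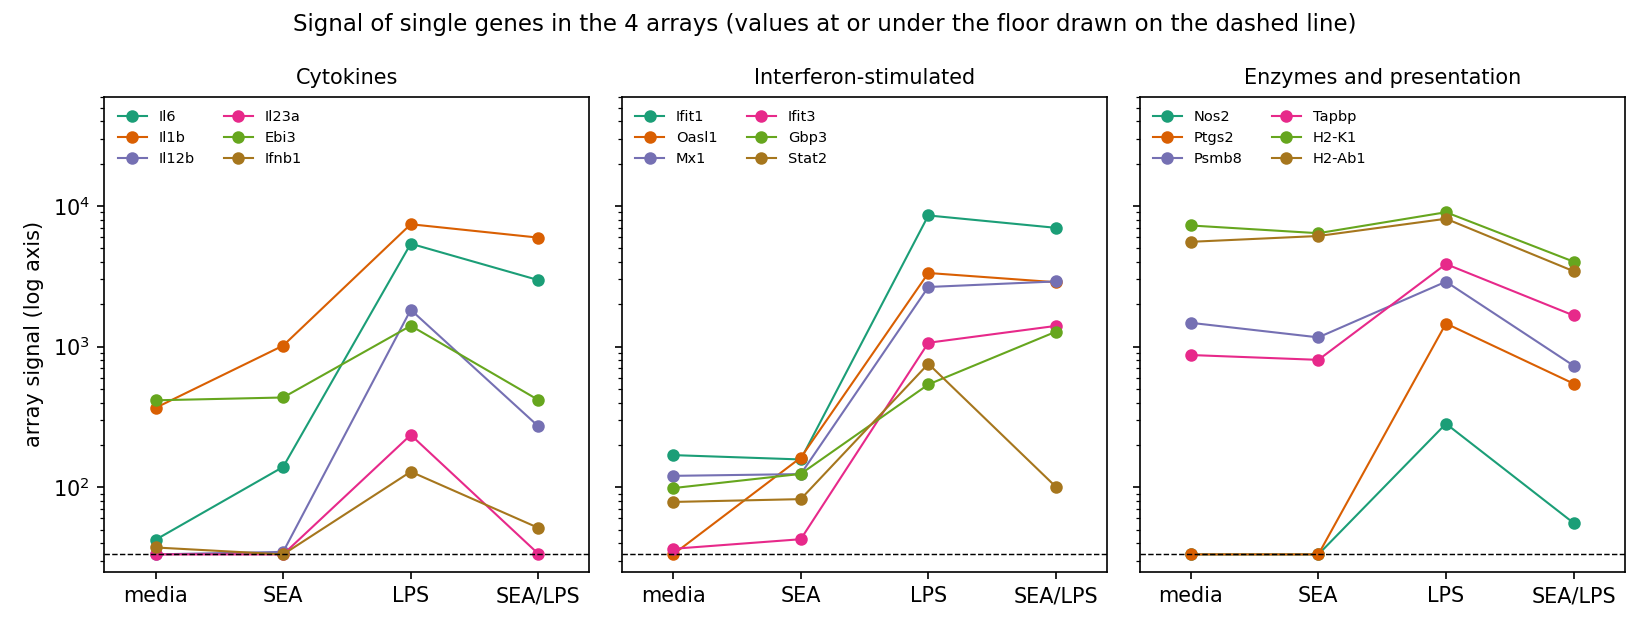
Array signal (log axis) of 6 cytokines, 6 interferon-stimulated genes and 6 enzymes or presentation genes in the media, SEA, LPS and SEA/LPS arrays, 1 array each; points at or under the floor of 33.3 are drawn on the dashed line. Il12b stood at 1827 with LPS and 271 with SEA/LPS, whereas Ifit1 stood at 8559.8 and 6988.

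The SEA difference was set side by side with and without LPS. Across genes these differences, which share no array, correlated with r = 0.02. The difference with LPS minus that without was at least 1 log2 in 299 genes and at most -1 in 620, a balance that turned to 784 and 243 when scaled to the hybridisation controls. For Stat2 it was -2.97, for Il6 -2.58 and for Cxcl1 -2.36. For Il12b, at the floor in media, it was at most -2.81, and for Idh1 it was 2.07. The other probe set of Idh1 read 0.56 with SEA over media and 0.26 with SEA/LPS over LPS, which is opposite in direction. Higher with SEA in both settings were 2 genes, Fen1 and Ciapin1, and 8 were lower in both, against 0.850 and 2.08 for independent lists. Without cross-hybridising probe sets Ciapin1 read -0.03 with SEA over media and -0.14 with SEA/LPS over LPS, and Fen1 read -0.11 in the latter, so this overlap of higher genes did not hold there.

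Marker lists of other cell types were measured as a check on the makeup of the samples. In LPS over media the medians were 0.00 for B cells, 0.05 for T cells, 0.27 for NK cells, 0.59 for neutrophils, 0.00 for mast cells, basophils and eosinophils, 0.22 for erythroid cells, -0.22 for macrophages and 0.33 for plasmacytoid dendritic cells. Of these, neutrophils lay outside their random range, at percentile 99.5, with Lcn2, an LPS-responsive gene, at 3.35 as the only one of 9 members past 2-fold, and their median stayed above 0 under every scaling tried. Macrophage markers had 2 of 10 members lower, the complement genes C1qa (-1.46) and C1qb (-1.17), and the other members past 2-fold were Tcf4 (2.25), Hdc (at least 3.89-fold higher) and Il2rb (at least 2.06-fold higher). The T cell, NK cell, erythroid and plasmacytoid medians were below 0 when scaled to the hybridisation controls. In SEA/LPS over media the neutrophil median was 0.37 (percentile 99.4), which turned to -0.083 with the floor at the 60th percentile, with Lcn2 (3.55) and S100a8 (1.10) higher. In SEA over media the erythroid median was 0.48 over 4 genes (percentile 99.7), with Epor at 0.62, Klf1 at 0.54 and Hba-a1, at the floor in media, at least 1.33-fold higher, and positive under every scaling tried. The other 7 lists there lay within their random ranges, as did all 8 in SEA/LPS over LPS, where 0 members passed 2-fold.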

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

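The test of the other probe sets of genes that differed with SEA was chosen only after the result was seen, and the test of a weak LPS response was set beforehand.

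SEA differences of opposite direction with and without LPS were found for 6 genes, each at least 2-fold higher with SEA than in media and at least 2-fold lower with SEA/LPS than with LPS. The SEA difference with LPS minus that without was -2.36 log2 for Cxcl1, -2.22 for Cyp4f13, -2.46 for Gckr, -2.17 for Lamb3, -2.62 for Rcor2 and -2.71 for Rtbdn. The values of Gckr and Rcor2, at the floor in media, and of Lamb3, Rcor2 and Rtbdn, at the floor with SEA/LPS, are upper bounds and have no order against the others. With 1 array per group these differences were not tested. Independent lists would share 2.12 such genes and simulated unchanged groups, in which few genes are called, shared 0.210 on average. Except for Cxcl1, signals of these genes stayed low, as for Gckr with 33.0 in media, 89.6 with SEA, 75.9 with LPS and 37.1 with SEA/LPS. The signals of Rcor2 in the same order were 18.1, 81.9, 83.2 and 15.9.

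The hybridisation control probe sets, which no comparison uses, were brighter on the LPS array than on the media array by 0.55 log2 (18 of 18 probe sets).

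The 121 genes that differed 2-fold with SEA alone were the first pattern weighed. Misreading by single probe sets may account for many of them: of 31 with another probe set above the floor, 12 (38.7%) pointed the same way there, inside the range of random genes (25.8% to 61.3%). The others include genes with no direction there. A candidate explanation for the inflammatory part is a weak form of the LPS response, for example endotoxin carried with SEA. The 100 genes highest with LPS and SEA/LPS had a median of 0.070 with SEA over media, just above the random range (-0.062 to 0.061, percentile 98.6), with 57 of them positive. Both stay open, as does an effect of SEA itself, which the design names and these tests do not separate from endotoxin.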

How the results depend on the processing

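Scaling to the hybridisation controls was chosen only after the data were seen, and all other settings were set beforehand. No paired analysis was possible because each group has 1 sample and shares only replicate number 1. Counts below give higher then lower genes for SEA over media, LPS over media, SEA/LPS over LPS, SEA/LPS over media and the SEA difference with LPS minus without. A 1.5-fold threshold gave 482 and 380, 1339 and 1985, 735 and 1271, 937 and 1917, and 1100 and 1690. A 3-fold threshold gave 5 and 3, 260 and 189, 16 and 49, 186 and 135, and 37 and 103. A floor at the 20th percentile gave 438 and 366, 1078 and 1290, 491 and 949, 729 and 1231, and 777 and 1497, with the LPS-high median at -0.24. With the floor at the 60th percentile the counts outside 1.5 times were 17 and 16 with SEA, 468 lower with LPS, 57 and 152 for SEA/LPS over LPS, 377 lower for SEA/LPS over media and 134 and 221 for the last, and the neutrophil median of SEA/LPS over media turned to -0.083. In these settings the threshold or floor itself admits more or fewer genes. Log2 of the signal plus the floor gave 34 and 30 with SEA, 518 lower with LPS, 72 and 185 for SEA/LPS over LPS, 404 lower for SEA/LPS over media, 191 and 334 for the last and an LPS-low median of 0.16. Of its genes with SEA, 23 and 18 were shared with the main setting, and the cause of these changes was not tested. Quantile normalization moved the LPS-low median to 0.20. Scaling to the 75th percentile gave 427 lower genes for SEA/LPS over media and an LPS-high median of -0.073. Scaling to the hybridisation controls gave 284 and 2431 with LPS, 103 lower with SEA, 299 and 134 for SEA/LPS over LPS, 1462 lower for SEA/LPS over media, 784 and 243 for the last and an LPS-low median of 0.29. It reversed the LPS-high median (0.074), the class II median of SEA/LPS over LPS (0.021) and the Notch median with LPS (-0.020). The IL-10 pathway medians with LPS (-0.23) and with SEA/LPS over media (-0.014) were reversed as well. The reason is that this scaling adds a constant to log2 differences between signals above the floor and alters which genes enter the sets. For SEA/LPS over LPS the constant was 0.24. Genes at the floor on both arrays stay at 0. Choosing the sets on LPS alone gave -0.38 and 0.43, and on SEA/LPS alone -0.011 and, reversed, -0.29, because the array used for choosing then enters the difference. The median of a gene's probe sets and leaving out cross-hybridising probe sets left the 12 counts and set medians within 1.5 times or within their interval. The former reversed Zmynd11 with SEA (-0.48), and the latter Cab39l with SEA (0.20), Ciapin1 with SEA (-0.026) and with SEA/LPS over LPS (-0.14), Fen1 (-0.11) and Mvd (-1.05) in SEA/LPS over LPS. For these single genes the cause was not tested. Of 844 list medians under other settings 806 stayed within the 95% interval over their members, but 61 had the opposite sign, 56 of them medians inside their random range as deposited, and of 2966 values of named genes 2778 held their direction and side of 2-fold. The share of the deposited signal near background limits what can be read: a gene with a signal at or under 33.3 has no order between arrays.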

Other observations

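The lists in this part and the test of a scale difference were chosen only after the result was seen, and the other tests below were set before their values were computed.

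Of 8 chemokine receptors 2 were higher with LPS than in media, 1 lower and 5 neither, and their median was 0.13 at percentile 80.1, or -0.20 when scaled to the hybridisation controls. Ccr7, which guides dendritic cells to lymph nodes, was higher by 1.99 log2 and Ccrl2 by 2.34, while Ccr2, a receptor for monocyte chemokines, had a difference of -3.12. With SEA/LPS over LPS, Ccr7 read -0.73 and Ccr2 1.15. For Ccr2, LPS minus the mean of media and SEA/LPS was -2.13 on the probe set used and only -0.50 on its other probe sets. Of 14 genes of fatty acid synthesis 5 were at least 2-fold lower with LPS and 0 higher: Scd2 (-2.51), Fads1 (-1.69), Mid1ip1 (-1.43), Fasn (-1.16) and Elovl5 (-1.03). Their median of -0.46 lay at percentile 5.40 and was negative under every scaling tried. Lysosome genes had 2 of 16 members lower with LPS, Npc1 (-1.19) and Tfeb, a regulator of lysosome genes (at least 3.86-fold), with a median of -0.43 at percentile 2.87. Of 15 apoptosis regulators the inhibitor Cflar (2.20) and the inflammatory caspase Casp4 (2.16) were higher with LPS, and the list median was 0.27, or -0.29 when scaled to the hybridisation controls.

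Aminoacyl-tRNA synthetases, which charge tRNAs for translation, had 5 of 18 members lower with LPS. These were Yars (-2.19), Iars (-1.86), Nars (-1.12), Vars (-1.04) and Farsb (at least 4.62-fold). The hypothesis that members not yet seen follow Sars, Vars and Yars was tested on the other 15, whose median was -0.47, with 10 negative and 3 at least 2-fold lower. Sars itself read only -0.35 with LPS over media. That median lay inside the range of random lists, whose lower end was -0.52, so the test does not set the family apart.

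Lower inflammatory genes beside level interferon-stimulated genes in SEA/LPS over LPS were the next pattern weighed. A linear fit was made on signal and on the size of the LPS response. The residual medians of 35 inflammatory and 29 interferon genes still differed by -0.50 (random -0.33 to 0.34). This argues against a linear trend with either as the whole cause, while a curved trend was not tested. Misreading by single probe sets is argued against, though narrowly, since the other probe sets of 12 inflammatory genes had a median of -0.37 with a random lower end of -0.33. A scale difference of the size of the hybridisation controls stays open for the lower cytokines taken alone. Scaling to these controls left their median at -0.37 with a 95% interval over members of -1.09 to 0.05. The interferon median then read 0.22. A constant cannot make the gap between the cytokine and interferon medians, which was -0.59 (random pairs of lists -0.40 to 0.21). This argues against such a scale difference as the cause of that gap. RNA quality, with the Gapdh ratio at 3.12 against 2.42 and the Actb ratio nearly level at 1.26 against 1.24, and differences between separate cultures were not tested and stay open, so that an action of SEA on the cytokine part of the LPS response may be one explanation and remains a hypothesis.

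Genes low on the LPS array alone, at least 2-fold under both media and SEA/LPS, numbered 94 and were the last pattern weighed. Single probe sets misread on that array could give such genes, and their other probe sets would then not follow. For 39 genes with other probe sets, the median there of LPS minus the mean of media and SEA/LPS was -0.37, under the random range (-0.16 to 0.17), while all 94 had a median of -1.40 on the probe sets used. This measure is also negative for a gene that is lower than media with both LPS and SEA/LPS. It therefore cannot tell whether the other probe sets dipped on the LPS array alone, and misreading stays open. The smaller size on other probe sets leaves room for it, as for Rusc1 (-2.96 against 0.01). By this measure Egr2 (-1.62 against -1.71), Idh1 (-2.95 against -1.31) and Tgfbi (-1.60 against -1.23) were low on both. The other probe set of Idh1 was low with SEA/LPS too (signal 249.1 in media, 48.2 with LPS and 57.7 with SEA/LPS). It thus did not show a dip on the LPS array alone. An error of the LPS sample as a whole was not tested and stays open.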
